A study of Gallus gallus with 12 samples.

How the data were processed

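Primary cultures of chicken erythrocytes, which are nucleated red blood cells, were incubated for 12 h without a stimulus or with lipopolysaccharide (LPS, a cell wall component of Gram-negative bacteria) at 50 µg/ml, peptidoglycan (PGN, a bacterial cell wall polymer) at 5 µg/ml or poly(I:C), a synthetic double-stranded RNA, at 50 µg/ml. Each of the 4 groups had 3 biological replicates, per the labels, and each RNA sample was labelled with Cy3 and hybridised to 1 one-colour Agilent array, giving 12 arrays. Per the labels' protocols, 150 ng of total RNA was amplified together with spike-in RNA. The labels do not say whether replicates came from separate birds, so p-values measure the spread between these cultures. In the main fit that spread also includes differences between the array slides, as described below.

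The deposited scanner files hold spot intensity on a linear scale, which Agilent Feature Extraction 10.7.3.1 had background-subtracted, detrended and given surrogate values where signals were small, per the file headers. Raw median intensities of spot and local background, and flags for spots well above background, outliers and saturation, came from the same deposited files. The authors' value table holds log2 values, deposited by the authors. Each column equals log2 of the background-subtracted signal of its array with a largest difference of 5e-09, and is empty where that signal was not positive. These values are absolute, with no centring and no scaling between arrays, and the column medians ran from 7.41 to 8.98. In the file of PGN replicate 3 the signals carry 3 significant digits, against 7 in the other 11 files. No spot was saturated.

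For the main analysis, log2 of the processed signal was taken, outlier spots were set to missing (333 probe values), spots of one probe were averaged, and the 75th percentile of each array was subtracted. A level below is therefore in log2 units relative to that percentile. Of 43603 non-control probes, 26302 were well above background on all 3 arrays of at least 1 group and were kept. For each gene the kept probe with the highest mean signal over all arrays was used, leaving 18559 genes or unnamed transcripts. Probes were named by matching their RefSeq accession, without version, to a table of the GRCg7b assembly, which was used for names alone because the file headers name galGal3. A symbol was found for 10425 probes. After the filter 3545 of the tested features (19.1%) had a symbol other than a LOC number, and 14985 had none, so gene lists and named genes cover a minor part of the array. Members of the gene lists were matched by symbol and otherwise by a synonym in the same table, and carry the table's symbol, so that a few stand for a related gene (SLC2A14 for the glucose transporter listed as SLC2A3). A value given for a gene is that of its brightest kept probe, and kept probes of a named gene that moved in opposite directions are stated. Probes of a named gene that did not pass the filter were not set beside it.

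Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 12 arrays in one fit, no block), with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. All p-values are two-sided. Each of 20 gene lists with at least 5 measured members was tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, leaving out the 151 genes with a missing value. Named genes followed a rule fixed before the data were examined, as were the groups, tests and lists. The rule took, for each comparison with the control, the 10 largest rises and 10 largest falls among genes with a symbol past the threshold whose 3 stimulated arrays all lay on the same side of the 3 controls; up to 4 members of each list past the threshold, or 2 with the smallest p where none passed; and 12 immune genes wherever measured. Of those 12, IFIT5, OASL and TLR15 had no probe with their symbol, the 1 probe of TLR3 did not pass the filter, and IL8 is listed as IL8L2. MMP9 and SERPINH1 fall outside the rule and were named after their values were seen, to complete short counts. Between stimuli it took the 5 largest differences in each direction. Where a probe was not well above background on any array of a group, the fold is given as a bound ("at least"), from the brighter group's mean against, per array of the dimmer group, the higher of the lowest signal among probes well above background and the probe's own.

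The 3 replicate numbers coincide with 3 slides, each scanned in 1 pass and each holding 1 array of every group. Replicates with the same number deviated together from their group means: all 18 same-number pairs had a correlation over 0.1 (0.33 to 0.69), pairs with different numbers ran from -0.44 to -0.02, and all 12 arrays correlated best with an array of their own number. The numbers therefore pair the arrays, through the slide, the culture or both. The fit with the replicate as a block is also the fit with the slide as a block. With 1 array per group on a slide no test within a slide was possible, and slide differences are given instead. Scan day, software version and protocol were the same on every array.

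The number of probes well above background ran from 17406 (poly(I:C) replicate 3) to 29503 (PGN replicate 3) per array, and the number of arrays limits the precision. On simulated arrays with the real means and residual spread, 27 of 100 genes changed by 1 log2 unit and 71 of 100 changed by 2 log2 units were called for poly(I:C) against control over 18408 genes, with 9 calls among the unchanged genes. No other genes were changed in this simulation, and its noise had no pairing by slide. The real comparison called 2777 of 18559 features, so its cutoff on the unadjusted p was less strict. The simulated shares are therefore not its detection rates. Alternatives covered background correction (normexp with an offset of 50, on the median spot signal, the column used here in place of the planned mean signal), quantile normalization, the filter, the authors' value table, the replicate block, only the 6 arrays compared, single probes, an intensity trend, array weights, a fold threshold and leaving out each array. Averaging the probes of a gene, and leaving out the 3 arrays of slide 3 with the fewest probes above background, were chosen after the data were seen, as was fry with the replicate block.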

Results

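Gene expression was measured in 12 cultures of chicken erythrocytes, 3 each without stimulus and after 12 h with LPS, PGN or poly(I:C). Between 39.9% and 67.7% of probes were well above background on an array. The fewest were found on poly(I:C) replicate 3 (17406), LPS replicate 3 (18219) and control replicate 3 (21040). Arrays of one group correlated at 0.94 or more across genes. The comparisons ask which transcripts the cells change in response to bacterial and viral mimics. Changes are log2 differences in mean from the control with n = 3 arrays per group, and adjusted p-values are from limma.

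With LPS, the largest rise among named genes was that of AVD, which encodes the biotin-binding protein avidin. It rose by 6.88 log2 units (SE 1.14, adjusted p = 0.00887), from -0.52 ± 0.60 in control to 6.36 ± 0.73 (SD, n = 3), and both other probes of the gene rose too (8.33 and 8.49). Other large rises were seen for MARCKSL1 (5.17), CD72L1 (4.45), IL2RA (3.97), SYTL1 (3.80), the decoy interleukin-1 receptor gene IL1R2 (3.64), G0S2 (3.47) and GNAT2 (3.37). In control, MARCKSL1 and CD72L1 were above background on 2 of 3 arrays and IL2RA, SYTL1, G0S2 and GNAT2 on 1. VTN was at least 6.04-fold and C3AR1L at least 3.41-fold higher, their control signals being not well above background; C3AR1L was above it on 2 of the 3 LPS arrays. EXFABP, a secreted lipocalin that binds iron chelators, fell by 6.49 (SE 0.908, adjusted p = 0.00492), from 6.08 ± 0.52 to -0.41 ± 0.20. Falls were also seen for PLAU (-2.61), KIAA1671 (-2.42), BCL2L10 (-2.40), the leukocyte integrin chain ITGB2 (-2.15), BTBD9 (-2.09), PITPNM3 (-2.04) and the transporter gene ABCC4 (-1.93), while LY86 was at least 3.86-fold lower. ARHGAP15 fell from -3.18 ± 0.48 in control to a level not above background on any LPS array. All of these genes passed the threshold, and their differences had the same sign on 3 of 3 slides.

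**Figure D1:**
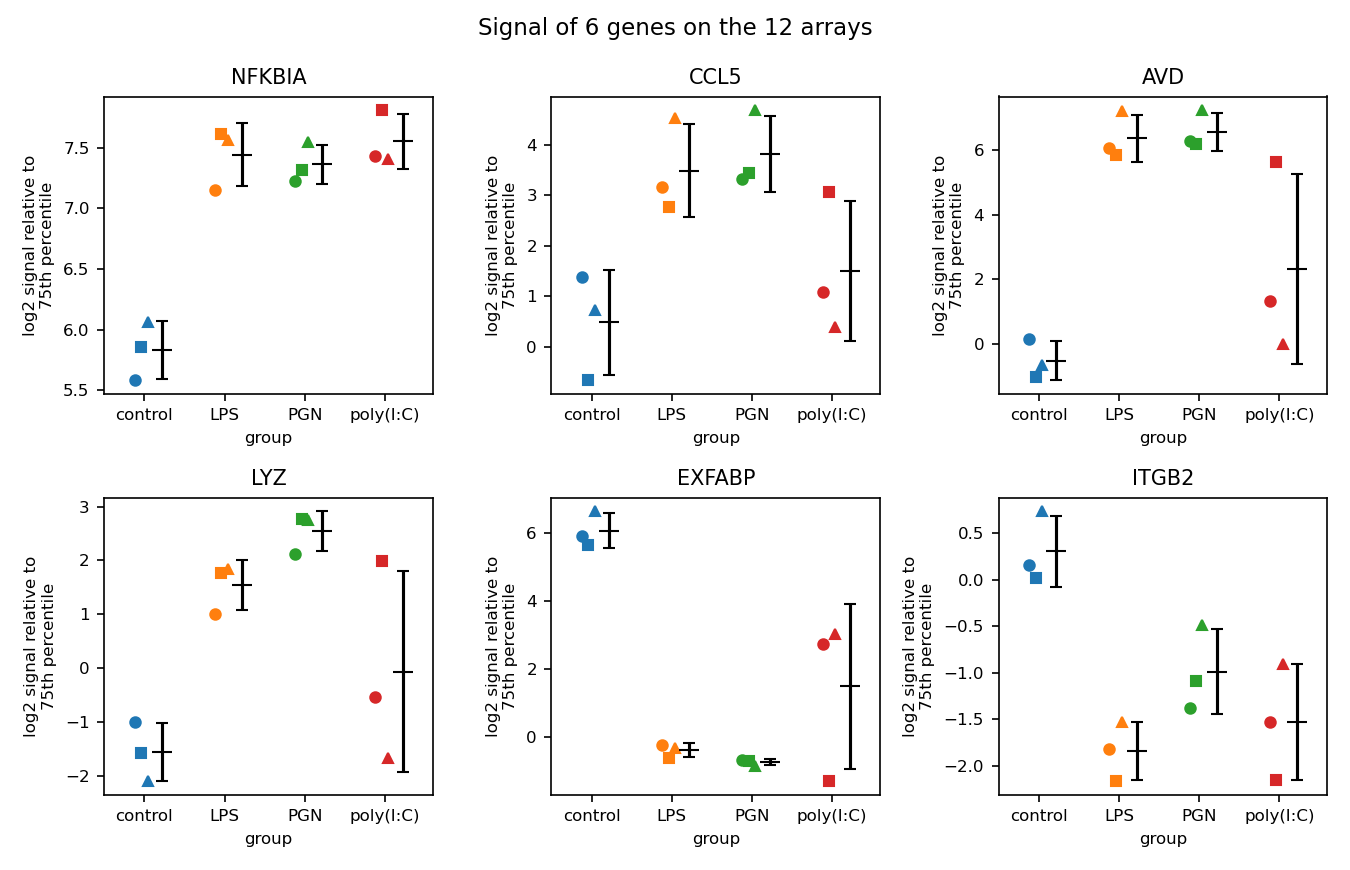
Log2 signal relative to the 75th percentile of the array (y axis) of 6 genes in the 4 groups (x axis). Circles, squares and triangles are replicates 1, 2 and 3, and the bar with its error is the group mean ± SD. EXFABP lies at 6.08 in the control mean and at -0.41 with LPS, and AVD reached 5.61 on poly(I:C) replicate 2 but 1.31 and 0.00 on the other poly(I:C) arrays.

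Of 18 measured inflammatory cytokines and chemokines, 2 rose with LPS (3 adjusted over the list alone) and none fell. These were CCL5, a chemokine for T cells and monocytes (3.01, adjusted p = 0.0414), and CSF3, a growth factor for granulocytes (1.33, adjusted p = 0.00446). IL1B (2.33, adjusted p = 0.38), IL6 (2.06, adjusted p = 0.238) and IL8L2 (2.51, adjusted p = 0.323) varied widely, and the slide differences of IL1B were -1.19, 3.74 and 4.45. Among 12 genes of NF-kappa-B signalling, the inhibitor NFKBIA (1.61, adjusted p = 0.00335) and the subunit NFKB2 (0.98, adjusted p = 0.0407) rose, the other NFKB2 probe moving by 0.24. Of 12 pattern recognition genes 1 passed, TLR7, with signal above background on 1 LPS array and no control array. TLR4, the LPS receptor gene, was at -0.86 (adjusted p = 0.0663, 0.0251 with the replicate block) and fell adjusted over the list alone. None of 16 interferon-stimulated genes passed the threshold, and with the replicate block 2 rose and 4 fell. The antiviral gene MX1 was at -1.15 (adjusted p = 0.211, 0.00669 with the replicate block) and the RNA sensor gene IFIH1 at -0.74 (adjusted p = 0.113, 0.000779 with the block). Of 10 interferon and receptor genes 1 fell, the receptor gene IFNAR1, by 0.78 (adjusted p = 0.0227), and none rose, while with the block 5 rose and 1 fell. As drawn up, this list also named the signalling genes JAK1, JAK2 and TYK2 and an interferon regulatory factor (IRF3 or IRF7). Its counts are therefore not of interferons and receptors alone. The interferon genes IFNA3 and IFNW1 were at 0.64 (adjusted p = 0.203, 0.00544 with the block) and 0.90 (adjusted p = 0.258, 0.00545 with the block), IFNW1 being above background on 1 LPS array. With the block the list passed by fry (adjusted p = 0.0284) but not by camera (adjusted p = 0.165, and adjusted p = 0.803 with an estimated correlation). Of 8 class I pathway genes CANX rose (0.97) and TAPBP fell by 0.89, and of 5 class II pathway genes CD74 rose (0.70), while the class I gene BF2 was at -0.21 (adjusted p = 0.793). Of 25 heat shock and unfolded protein genes 4 rose, among them HSPB1 (1.59), HSF2 (1.40) and HSP90B1 (0.83), and none fell. With the block 4 cytokines and chemokines rose and 1 fell, as in NF-kappa-B signalling, 1 pattern recognition gene rose and 6 fell, 1 class I pathway gene rose and 2 fell, and 6 heat shock genes rose and 1 fell.

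Of 24 measured erythroid genes, 1 fell with LPS, XK (-0.79, adjusted p = 0.0438), which encodes a red cell membrane protein; none fell adjusted over the list alone, and with the replicate block 1 rose and 7 fell. Among 21 monocyte and heterophil markers 1 rose, the lysozyme gene LYZ, from -1.56 ± 0.54 to 1.54 ± 0.46, and 4 fell, EXFABP, ITGB2, PLAU and MMP9 (2 rose and 4 fell adjusted over the list alone). None of 13 lymphocyte or 7 thrombocyte markers passed the threshold. With the block 3 monocyte and heterophil markers rose and 6 fell, 3 lymphocyte markers rose, and 1 thrombocyte marker rose and 1 fell. In total LPS raised 781 and lowered 711 of 18559 features, and with the replicate block 2955 and 3103. No list shifted as a whole in camera (lowest adjusted p = 0.127, for inflammatory cytokines and chemokines; adjusted p = 0.767 with an estimated correlation), with or without the replicate block, but 4 lists did without the filter on dim probes and 1 without LPS replicate 1. By fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes, no list passed without the block and 4 passed with it, among them NF-kappa-B signalling (adjusted p = 0.0407) and, downward, monocyte and heterophil markers (adjusted p = 0.0173). For these 2 lists camera with the block gave adjusted p = 0.226 and 0.165 at the preset correlation, and 0.803 for both with an estimated correlation. The count of changed features ranged from 602 without LPS replicate 3 to 1605 without poly(I:C) replicate 3, was 139 without the 3 arrays with the fewest probes above background, and was 399 with normexp background correction (125 higher, 274 lower).

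Of the 10 named genes with the largest rises under PGN, 7 were also among the 10 largest under LPS. AVD rose by 7.08 (SE 1.14, adjusted p = 0.00954), MARCKSL1 by 5.56, CD72L1 by 4.88, IL1R2 by 4.06, G0S2 by 3.92 and GNAT2 by 3.73. LYZ, not among the largest rises with LPS, rose by 4.11. C3AR1L was at least 6.61-fold, LPAR2 at least 6.52-fold and GRIA2 at least 2.75-fold higher, and the other LPAR2 probe moved by 0.83. EXFABP fell by 6.84 (SE 0.908, adjusted p = 0.00443). EMB was at least 5.40-fold lower, and KIAA1671 (-2.40), LY86 (-2.02), BTBD9 (-2.02), BCL2L10 (-1.84), ABCC4 (-1.82), LDAH (-1.74), PITPNM3 (-1.71) and KCNN2 (-1.64) fell. Of 18 cytokines and chemokines 3 rose (4 adjusted over the list alone): CCL5 (3.33), CSF3 (1.37) and CCL20 (1.22). IL1B was at 2.04 (adjusted p = 0.469), IL6 at 2.45 (adjusted p = 0.164, 0.046 with the block) and IL8L2 at 2.68 (adjusted p = 0.297). Of 12 genes of NF-kappa-B signalling NFKBIA (1.53) and NFKB2 (1.16, its other probe 0.49) rose (3 adjusted over the list alone). Of 12 pattern recognition genes 1 rose: TLR7, a receptor for single-stranded RNA, was at least 2.05-fold higher (adjusted p = 0.00643), its control signal not being well above background; with normexp it was at 0.32 and did not pass the threshold. TLR4 was at -0.43 (adjusted p = 0.37).

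None of 16 interferon-stimulated genes and none of 24 erythroid genes passed the threshold with PGN, and with the replicate block 1 and 2 of them rose and 4 and 8 fell. MX1 was at -0.93 (adjusted p = 0.334, 0.0159 with the block). IFNAR1 fell by 0.67, 1 of 10 interferon and receptor genes, and none rose (2 adjusted over the list alone), while with the block 3 rose and 1 fell. IFNA3 was at 0.87 (adjusted p = 0.0894, 0.00181 with the block) and IFNW1 at 1.36 (adjusted p = 0.0916, 0.00126 with the block). With the block the list passed by fry (adjusted p = 0.0235) but not by camera (adjusted p = 0.205, and adjusted p = 0.858 with an estimated correlation). Of 8 class I pathway genes CANX rose (0.93) and TAPBP fell by 0.84 (2 rose and 1 fell adjusted over the list alone), and of 5 class II pathway genes CD74 rose (0.69). BF2 was at -0.31 (adjusted p = 0.682, 0.0412 with the block). Of 21 monocyte and heterophil markers LYZ and the transcription factor gene CEBPB (1.57) rose and EXFABP fell (5 rose and 4 fell adjusted over the list alone), and none of 13 lymphocyte or 7 thrombocyte markers passed. The heat shock genes HSPB1 (1.66), HSF2 (1.52), HSP90B1 (0.82) and HSPA9 (0.52) rose out of 25. With the block 7 cytokines and chemokines rose and 1 fell, 4 genes of NF-kappa-B signalling rose and 1 fell, 2 pattern recognition genes rose and 2 fell, 2 class I pathway genes rose and 3 fell, 2 class II pathway genes rose and 7 heat shock genes rose. Of the markers, 4 of monocytes and heterophils rose and 5 fell, 3 of lymphocytes rose, and 1 of thrombocytes rose and 1 fell. HIF1A, the hypoxia-response transcription factor gene, rose by 1.81, its 4 other probes by 0.21 to 2.39. PGN raised 942 and lowered 462 features, and 3538 and 2262 with the replicate block. No list shifted as a whole in camera (lowest adjusted p = 0.149; adjusted p = 0.782 with an estimated correlation), with or without the replicate block, but 5 lists did with normexp and 7 without the filter on dim probes. By fry 0 lists passed without the replicate block and 9 with it, among them NF-kappa-B signalling (adjusted p = 0.0249), lymphocyte markers (adjusted p = 0.0272) and inflammatory cytokines and chemokines (adjusted p = 0.0311). For these 3 lists camera with the block gave adjusted p = 0.205, 0.286 and 0.286 at the preset correlation, and 0.858 for each with an estimated correlation. The count ranged from 356 without PGN replicate 3 to 1471 without poly(I:C) replicate 3, and was 479 with normexp (218 higher, 261 lower).

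Poly(I:C) raised 1363 features and lowered 1414, more than LPS or PGN, but with array weights it changed 2337 against 2409 for PGN. NFKBIA rose by 1.72 (SE 0.20, adjusted p = 0.00088), from 5.84 ± 0.24 to 7.55 ± 0.23, and CSF3 by 1.07, the only 1 of 18 cytokines and chemokines past the threshold. NFKBIE, an inhibitor related to NFKBIA, fell by 1.42. The interferon gene IFNA3 rose by 1.14 (adjusted p = 0.0219), although its 2 other probes moved by -0.02 and 0.29. IFNW1 was at 1.03 (adjusted p = 0.145, 0.00222 with the block), above background on 1 poly(I:C) array. None of 16 interferon-stimulated genes passed the threshold, and with the block 2 rose and 5 fell. The cytokine signalling inhibitor SOCS1 was at 0.89 (adjusted p = 0.0613, 0.00107 with the block) and the double-stranded RNA-dependent kinase gene EIF2AK2 at -0.39 (adjusted p = 0.145, 0.0285 with the block). MX1 was at -1.13 (adjusted p = 0.173, 0.00541 with the block), a fold of at least 1.48, since it was not above background on any poly(I:C) array. IFNAR1 fell by 0.89; of 10 interferon and receptor genes 1 rose and 1 fell, and 4 rose and 1 fell with the block. With the block the list passed by fry (adjusted p = 0.0261) but not by camera (adjusted p = 0.281, and adjusted p = 0.728 with an estimated correlation). Of 12 pattern recognition genes 1 passed, TLR7, which was not above background in either group. TLR4 was at -0.83 (adjusted p = 0.053, 0.0227 with the block) and fell adjusted over the list alone. Of 8 class I pathway genes 3 rose, PDIA3 (1.43), CANX (0.89) and B2M (0.66), and TAPBP fell by 0.77. BF2 was at 0.06 (adjusted p = 0.933) and its other probe at -0.22. Of 5 class II pathway genes CD74 rose by 0.65.

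EXFABP fell by 4.60 with poly(I:C) (adjusted p = 0.00871), with slide differences of -3.18, -6.98 and -3.63. ATP1B1 (-3.36), PDE4B (-2.79), ZBTB43 (-2.46), BTBD9 (-2.41), KIAA1671 (-2.31), FAM65B (-2.24), PITPNM3 (-1.95), KCTD20 (-1.93) and CRYBB3 (-1.92) fell, and of the 3 other ATP1B1 probes 1 moved the other way (0.66). Of 21 monocyte and heterophil markers CEBPB rose (1.24, its other probe 0.44), and ITGB2 (-1.84), PLAU (-1.77) and CYBB (-1.31) fell with EXFABP (3 rose and 6 fell adjusted over the list alone). Of 13 lymphocyte markers 1 fell, PTPRC, not above background with poly(I:C), and none of 7 thrombocyte markers passed. Of 24 erythroid genes XK fell by 1.11, and with the block 1 erythroid gene rose and 8 fell. Of 25 heat shock and unfolded protein genes 4 rose, among them HSF2 (1.52) and the chaperone gene HSPA5 (1.22), and SERPINH1 fell by 0.67 (5 rose and 1 fell adjusted over the list alone). With the block 4 cytokines and chemokines rose and 1 fell, 5 genes of NF-kappa-B signalling rose and 1 fell, 2 pattern recognition genes rose and 4 fell, 2 class II pathway genes rose, and 8 heat shock genes rose and 5 fell. Of the markers, 3 of monocytes and heterophils rose and 7 fell, 2 of lymphocytes rose and 2 fell, and 1 of thrombocytes rose and 1 fell. IL1B was at -1.74 (adjusted p = 0.464), with slide differences of -6.39, 3.02 and -1.85. IL8L2 was at -1.14 (adjusted p = 0.638), and IL6 (adjusted p = 0.82) was not above background on any poly(I:C) array. On poly(I:C) replicates 1, 2 and 3 IL8L2 lay at levels of -4.42, 0.80 and -3.035, and CCL5 at 1.08, 3.05 and 0.38. The mean changes of these genes thus hide replicates that disagree.

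Among genes with a value on every array, the largest rises with poly(I:C) were PRKAG3 (11.04), UHRF1BP1L (9.52), BARD1 (7.96), ITGB5 (7.96) and MIXL1 (6.55), with ENTPD2 at least 106.2-fold, VTN 19.8-fold, STK24 15.6-fold, TFAP2A 12.8-fold and EDIL3 11.5-fold higher as lower bounds. CHST3, with no value on 1 control array, was 9.73 above the mean of the other 2. In control, PRKAG3, UHRF1BP1L and BARD1 were above background on 2 arrays and ITGB5 on 1. On the same arrays a spike-in control probe, which reads added RNA and no chicken gene, was 4.84 log2 units above control. The 2 other PRKAG3 probes moved by -0.05 and 0.25 and the other MIXL1 probe by 0.58. Of the 4 ENTPD2 and 2 ITGB5 probes on the array, only the probe used for each gene passed the filter. The rises of these genes therefore rest on a single probe each. For GAPDH, 1 probe rose by 1.94 and the 4 others moved by 0.09 to 0.18. The counts with the replicate block were 3604 higher and 4254 lower, and 1184 features were changed with normexp. Leaving out 1 array gave 1736 (without control replicate 2) to 2792. No list shifted as a whole in camera (lowest adjusted p = 0.365; adjusted p = 0.742 with an estimated correlation), with or without the replicate block. By fry 0 lists passed without the block and 8 with it, among them NF-kappa-B signalling (adjusted p = 0.0261), the MHC class I pathway (adjusted p = 0.0302) and, downward, erythroid genes (adjusted p = 0.0474). For these 3 lists camera with the block gave adjusted p = 0.281, 0.334 and 0.334 at the preset correlation, and 0.728 for each with an estimated correlation.

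**Figure D2:**
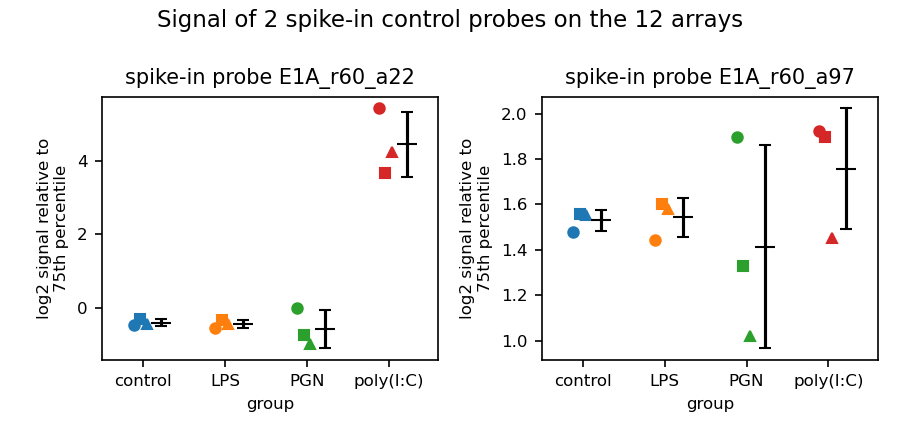
Log2 signal relative to the 75th percentile (y axis) of 2 control probes for spike-in RNA in the 4 groups (x axis), with symbols as for the genes and bars for the group mean ± SD. Probe E1A_r60_a22 had a mean of 4.44 on the poly(I:C) arrays and -0.40 on the control arrays, and E1A_r60_a97 had means of 1.76 and 1.53.

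Between stimuli, no feature differed between LPS and PGN at adjusted p 0.05 in limma, with 347 at an unadjusted p under 0.05; 2 passed with array weights, 4 with only the 6 arrays compared and 10 without control replicate 1. IL2RA and SYTL1, raised by LPS, were at -1.38 ± 1.49 and -1.46 ± 1.94 with LPS and at -7.31 ± 0.36 and -7.26 ± 0.42 with PGN (SD, n = 3), above background on no PGN array, and the differences between these stimuli did not pass (adjusted p = 0.376 and 0.381). Negative control spots averaged -7.841 on the PGN arrays and -5.835 on the LPS arrays, so the size of these 2 gaps depends on the lower PGN floor. Doses of these stimuli differed. Poly(I:C) differed from LPS in 147 features (128 higher, 19 lower) and from PGN in 198 (162 higher, 36 lower). The named genes among the largest were all higher with poly(I:C): PRKAG3 by 9.79 and 10.37 over LPS and PGN, UHRF1BP1L by 9.26 and 8.74, and CHST3 at least 300.9-fold over LPS. BARD1 (7.82 over LPS), ITGB5 (7.71 over PGN) and ENTPD2 (at least 49.8-fold over LPS, 187.4-fold over PGN) followed, and the spike-in probe was brighter on the same arrays. The 2 other PRKAG3 probes moved by -0.31 and 0.01 against LPS and by -0.17 and -0.12 against PGN. With the replicate block the counts were 421 and 1163, of which 200 and 829 were lower with poly(I:C). With quantile normalization 157 features were higher and 77 lower against PGN. Without poly(I:C) replicate 2 the counts were 280 and 412; without LPS replicate 2, 87 features differed from LPS, and without PGN replicate 3, 78 differed from PGN.

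The responses were compared across 18408 genes, which are not independent replicates. Changes under LPS and PGN correlated at 0.788, poly(I:C) and LPS at 0.646 and poly(I:C) and PGN at 0.587. Unchanged groups simulated against shared controls, which were simulated too, gave 0.499, 0.496 and 0.497. Without the filter on dim probes the correlations were 0.1388, 0.7236 and 0.06817 in the same order, so that their order turned and 2 fell below those simulated values, which were made with the filter. The negative control spots, not above background on any array, differed from control by 1.121 with LPS, -0.8848 with PGN and 1.459 with poly(I:C). The floor thus moved alike with LPS and poly(I:C) and the other way with PGN. Whether dim probes at this floor turned the order was not tested. With normexp poly(I:C) correlated with LPS at 0.5419 and with PGN at 0.5276. On the 3 slides taken singly the correlations were 0.819, 0.740 and 0.635 for LPS and PGN, 0.582, 0.640 and 0.541 for poly(I:C) and LPS, and 0.590, 0.594 and 0.518 for poly(I:C) and PGN. Unchanged groups simulated against 1 shared simulated control array gave a mean of 0.498 and at most 0.518, against which the last of these is close. The covariances were 0.390, 0.451 and 0.408 against 0.113, 0.112 and 0.112 simulated without the replicate block. Simulated with the block they were 0.06095, 0.06091 and 0.06088. Of the features raised, LPS and PGN shared 711, poly(I:C) and LPS 587 and poly(I:C) and PGN 666, where independent lists of these sizes would share 39.6, 57.4 and 69.2. Of those lowered they shared 448, 632 and 445, against 17.7, 54.2 and 35.2. No feature was changed in opposite directions by any pair of stimuli, and 565 were raised and 435 lowered by all 3. The 3 control arrays could not be divided into groups of at least 2, so part of the excess may come from the shared controls.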

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

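The tests of explanations in this part were chosen after the results were seen, and the splits of the arrays before. Of the control probes, which no comparison used, the following were brighter on every array of a stimulus than on any control array, with a mean difference over 1 log2 unit and signal well above background on all 3 arrays of the stimulus. With poly(I:C), spike-in probe E1A_r60_a22 was 4.84 log2 units above control and control probes DCP_22_0, DCP_22_2, DCP_22_4, DCP_22_6, DCP_22_7 and DCP_22_9 were 4.72, 5.17, 5.18, 6.30, 7.60 and 8.39 above it. DCP_22_9 was not above background on any control array and DCP_22_7 on 2 of 3, so that these differences, the former above all, are no exact folds. Probe E1A_r60_a20 was 2.05 above control, and DCP_20_0 and DCP_20_1 were 1.96 and 2.01 above it. Poly(I:C) replicate 1 carried these 3 means: E1A_r60_a20 was at 2.251 on it and at -1.583 and -1.168 on replicates 2 and 3, against -2.22 in control. DCP_20_0 was at 2.074, -1.642 and -1.125 and DCP_20_1 at 2.113, -1.753 and -1.213 in the same order. Control probe ETG05_66023 was 2.904 log2 units above control with PGN. It was also 3.22 above with poly(I:C) and 2.22 with LPS, on every array over every control, but above background there on 2 and 1 arrays; on the control arrays it was not above background, so that these too are no exact folds.

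A candidate explanation for the first of these, and for 122 features that were higher with poly(I:C) than in every other group, is labelled material derived from poly(I:C) that binds particular probe sequences. The lowest poly(I:C) array exceeded the highest other array by 3.67 log2 units at E1A_r60_a22, which does not show that the same holds for the 122 features. More spike-in RNA on these arrays is argued against by the other E1A probes, whose median rise was 0.277. Induction of the named transcripts stays open: the other probes of these genes rose by a median of 0.187 (9 of 42 by at least 1), but so low a value does not exclude it, because the other probes of genes raised by LPS and PGN rose by a median of only 0.40 (23 of 75). The other probes in both sets were taken without the filter on dim probes. Negative control spots differed from control by 1.459 with poly(I:C), 1.121 with LPS and -0.8848 with PGN. The medians and counts of other probes were therefore not taken at a like floor. Without the 122 features poly(I:C) raised 1241.

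Whether the cytokine, avidin and lysozyme changes come from other blood cells was not tested. A rule set after the counts were seen asks for more falls than rises of their markers, with and without the replicate block, to argue against a like gain of all. By that rule such a gain stays open under LPS and PGN. The median change of the 41 markers was -0.266 with LPS and 0.176 with PGN, far below the rises of AVD and CCL5 given above. These medians argue against a like gain of all these cells as large as those rises. They do not argue against a smaller gain or a gain of a single cell type. Nor do they bear on a rise of these genes within other blood cells already present, without any gain of cells. LYZ, a gene to be explained, is itself among the 41 markers. Of 41 markers 4 fell and 1 rose with LPS, and 1 fell and 2 rose with PGN; with the block 7 fell and 7 rose with LPS, and 6 fell and 8 rose with PGN. With the block 6 of 21 monocyte and heterophil markers fell and 3 rose with LPS, and 5 fell and 4 rose with PGN, while 3 of 13 lymphocyte markers rose and none fell under either. Control levels were 6.08 for EXFABP and 3.87 for the T cell gene CD3D. Of the 41 markers 27 were well above background on all control arrays, so RNA of other blood cells, or expression of these genes in erythrocytes, was present before stimulation.

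Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. Poly(I:C) called 2777 features against at most 1 in another split, LPS 1492 and PGN 1404 against 0. Poly(I:C) and LPS differed in 147 against 0, and poly(I:C) and PGN in 198 against 1. In each of these 5 comparisons 1 split, the real one, reached its count. Every other split mixes arrays of both groups on each side, so a real difference adds to the spread and lowers the count. The low counts of the other splits therefore do not measure chance. For LPS against PGN all 10 gave 0. Of the 10 splits 4, the real one included, part all 3 same-number pairs, and the other 6 part 1 pair.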

How the results depend on the processing

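The arrays left out of slide 3 and the averaging of probes were chosen after seeing the data, as was fry with the block, and the other alternatives before. Without the filter on dim probes 31523 features were tested, and the counts were 1377, 421 and 341 for poly(I:C), LPS and PGN against control, 97 for poly(I:C) against LPS and 115 against PGN, with 4 lists called under LPS and 7 under PGN and similarities of 0.7236 (poly(I:C) and LPS), 0.06817 (poly(I:C) and PGN) and 0.1388 (LPS and PGN). With only probes above background on all 12 arrays, 71 and 94 features differed between poly(I:C) and LPS or PGN. With normexp 1184, 399 and 479 features changed under the 3 stimuli, 120 differed between poly(I:C) and PGN, 5 lists were called under PGN, the similarities of poly(I:C) with LPS and PGN were 0.5419 and 0.5276, and TLR7 was at -0.1687 with poly(I:C) and -0.01607 with LPS, turning its direction. With the replicate block 7858, 6058 and 5800 features changed, and 421 and 1163 differed between poly(I:C) and LPS or PGN; the block turned no called direction and ended no named call, and 43 named results under the threshold passed it with the block. By fry with the block 8, 4 and 9 lists were called under poly(I:C), LPS and PGN.

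With only the 6 arrays compared 1065 features changed under poly(I:C), 325 under LPS, 35 and 131 differed between poly(I:C) and LPS or PGN, and 4 between LPS and PGN, from fewer arrays. Array weights gave 2409 under PGN, over the 2337 under poly(I:C), and 2 between LPS and PGN. A log2 change of at least 1, a stricter rule, left 1735, 943 and 878. Without the 3 arrays of slide 3 with the fewest probes above background the counts were 1245, 139 and 725, and 78 and 110 between poly(I:C) and LPS or PGN. Apart from those with fewer arrays or a stricter rule, the cause was not tested.

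Leaving out 1 array gave 1736 to 2792 features for poly(I:C), 602 to 1605 for LPS, 356 to 1471 for PGN, 87 to 280 for poly(I:C) against LPS, 78 to 412 for poly(I:C) against PGN and 0 to 10 for LPS against PGN (10 without control replicate 1). No list was called by camera under poly(I:C) or PGN, and 0 to 1 under LPS. Similarities ran from 0.5866 to 0.6717, 0.5344 to 0.6139 and 0.7079 to 0.8161 for poly(I:C) with LPS, poly(I:C) with PGN and LPS with PGN. Of the named gene results 22 lost the threshold with quantile normalization, 18 with the authors' value table, 66 with normexp and 75 without the filter. The losses were 74 with only the 6 arrays compared and 85 without the 3 arrays of slide 3. They were 15 with averaged probes, 8 with array weights and 7 with an intensity trend. Over all fits with 1 array left out, counted together, a named result lost the threshold 430 times, gained it 5 times and stayed the same 2049 times. No called direction turned except that of TLR7 with normexp. The other alternatives run for a count kept it within 1.5 times. Lists and similarities were run with the block, normexp, quantile normalization, no filter and 1 array left out, and lists also with an estimated correlation and fry. Signal was well above background on all 12 arrays for 15804 of 43603 probes, and for a group with no array above it a fold is only a bound.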

Other observations

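The lists not described above had few members past the threshold without the replicate block and more with it. With poly(I:C), 2 of 23 proteasome genes rose (PSME3 by 0.58 and PSMC3 by 0.51, with another PSMC3 probe at 0.07), and none of 28 ribosomal protein genes and none of 21 genes of iron handling and redox passed the threshold under any stimulus; with the block 8, 3 and 2 ribosomal protein genes rose and 1, 3 and 1 fell with poly(I:C), LPS and PGN. With LPS no proteasome gene passed over all genes and 2 rose adjusted over the list alone, and with PGN PSMC3 rose by 0.49, with another probe at 0.16, but not adjusted over the list alone. The ATP synthase genes ATP5F1AZ (0.88, 0.79 and 0.85 under poly(I:C), LPS and PGN) and ATP5B (0.58, 0.64 and 0.76) rose under each stimulus, while the median of the 18 measured oxidative phosphorylation genes was -0.24, -0.34 and -0.24, and ATP5I fell by 0.96 with LPS. With the block 7, 10 and 9 of the 18 fell and 2, 2 and 3 rose, and by fry with the block the list passed downward (adjusted p = 0.0261, 0.0125 and 0.0272), but not by camera with the block (adjusted p = 0.325, 0.0835 and 0.0793; adjusted p = 0.728, 0.803 and 0.858 with an estimated correlation). The glycolytic gene PGAM1 rose by 0.90, 0.79 and 0.73 and SLC2A14 fell by 0.67, 0.73 and 0.66; of the 16 genes of glycolysis and hypoxia response 2, 1 and 2 rose and 2, 1 and 1 fell (2, 1 and 4 rose and 3, 2 and 1 fell adjusted over the list alone). Of 9 immediate-early genes CEBPB rose and KLF6 fell by 1.10 with poly(I:C) (2 rose and 1 fell adjusted over the list alone), CEBPB rose with PGN, and none passed with LPS. Of 31 histone and replication genes 2 rose and 1 fell with poly(I:C), and 1 rose with LPS and with PGN, but none passed adjusted over the list alone under any stimulus. Of 21 apoptosis genes AIFM1 fell by 0.64, 0.55 and 0.56, and DIABLO fell with poly(I:C), to a level not above background, though not adjusted over the list alone; with the block 4, 3 and 4 rose and 8, 4 and 3 fell. In the same order 7, 5 and 8 proteasome genes rose with the block and 4, 2 and 2 fell, 5, 3 and 5 genes of iron handling and redox rose and 4, 4 and 2 fell, and 8, 6 and 7 histone and replication genes rose and 3, 4 and 4 fell. Of the immediate-early genes 3, 2 and 2 rose with the block and 2, 1 and 0 fell, and of glycolysis and hypoxia response 2, 2 and 4 rose and 3, 3 and 2 fell.

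For several genes poly(I:C) replicate 2 lay near LPS and PGN and the other poly(I:C) replicates did not: AVD was at 5.61 against 1.31 and 0.00, and LYZ at 1.98 against -0.53 and -1.66. CCL5 was at 3.05 against 1.08 and 0.38, and IL8L2 at 0.80 against -4.42 and -3.035. CD72L1 was at 0.19 against -2.66 and -4.67, IL1R2 at 0.29 against -1.105 and -2.70, and G0S2 at -1.57 against -4.14 and -4.65. NFKBIA, at 7.81 against 7.435 and 7.41, did not show this. The genes named here were chosen after their values were seen, as was the test. Over all 191 genes changed by more than 2 log2 units by both LPS and PGN, the slope of the poly(I:C) change on theirs was 0.834 in replicate 2 and 0.994 and 0.844 in replicates 1 and 3, with no array shared by the changes compared. A simulated unchanged group, with genes of both directions chosen by the same rule, gave at most 0.146. Over the 171 raised genes, for which no simulation was run, the slopes were 0.819, 1.02 and 0.840 in the same order. The simulation held no shift of the floor, while negative control spots were 1.459 above control on the poly(I:C) arrays. How much of the slopes this higher floor gives was not tested. The simulated value is therefore no bound for an unchanged group on these arrays. Over that set slopes of this size were not particular to replicate 2, whatever their source. The genes were chosen by a fit whose spread includes the poly(I:C) arrays. Genes moved in replicate 2 alone therefore tended to be left out, and for them the test cannot decide. Without replicate 2, 280 features differed between poly(I:C) and LPS and 412 between poly(I:C) and PGN, against 147 and 198 with it. The values of AVD, LYZ, CCL5, IL8L2, CD72L1, IL1R2 and G0S2, and of MARCKSL1 (0.87 against -1.73 and -3.43), stay without a tested explanation.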
